A study of Mus musculus with 8 samples.

How the data were processed

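Open chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in 8 libraries of the mouse melanoma cell line YUMMER1.7. This BRAF-mutant line lacks Pten and Cdkn2 and carries many mutations induced by ultraviolet light. The libraries form 4 groups of 2, taken from the labels: control cells, control cells given interferon-gamma (IFNG), Kdm5b knockout (KO) cells, and KO cells given IFNG. The labels give neither the dose nor the duration of IFNG, and they do not say whether the 2 libraries of a group came from separate cultures, so the replicates may be technical. The labels call the first KO replicate deletion 1 and the second deletion 2, while the deposited files name a single clone, so it is not known whether the KO group holds 1 or 2 deletions.

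The deposited table holds, per the file headers, the whole-number count of transposase insertion sites in each of 146899 regions of 1 peak set merged over all libraries, made by the authors with featureCounts 1.6.2 and not normalised. The submitters' processing notes name CASAVA, Trimmomatic, Bowtie2, SAMtools, MACS3, featureCounts and deepTools and the genome build mm10, without parameters. The regions had a median length of 377 bp. Totals ran from 43010015 to 129948916 counts per library, and the median region held between 81 and 259 counts per library. The common biological coefficient of variation between libraries was 14.8%, on 4 residual degrees of freedom, while the counting error at the median count was 6.21% to 11.1%. Below about 45.8 counts the counting error was the larger, so it set much of the precision for regions with few counts.

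Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, after being read in Python 3.11.15 with pandas 2.3.3 and NumPy 2.4.6. Figures were drawn with matplotlib 3.10.9. The edgeR fit used TMM composition factors, the filterByExpr filter, which removed no region, robust dispersion estimates and a mean per group over all 8 libraries. Each of 5 contrasts was tested with the two-sided quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over all 146899 regions with a threshold of 0.05. The contrasts were KO against control without IFNG, KO against control with IFNG, IFNG against untreated in control cells, IFNG against untreated in KO cells, and the difference of the last pair. Standard errors are the fold change divided by the root of the F statistic, on the log2 scale. Levels are TMM-scaled CPM (counts scaled to a common library total), as mean ± SD.

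The only annotation available was a RefSeq gene table for GRCm38.p6 without strand, transcripts or sequence. The planned region at the transcription start of a gene was therefore replaced by its gene-end region, the region within 1 kb of either annotated end of a protein-coding gene with the highest mean count. Such a region was found for 14155 of 21900 protein-coding genes, and it lay at the end with the lower coordinate in 7127 of them. Some gene-end regions lie at the 3′ end of their gene. The planned tests of sequence motifs and of repeat-masked bases could not be run without a genome sequence, so retroelements were not analysed here.

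There were 22 gene lists, each tested on its gene-end regions with limma's camera at a preset correlation of 0.01, adjusted over the 22 lists of a contrast. The tests were also run with the correlation estimated from the data. The lists were MHC class I antigen presentation, MHC class II antigen presentation, interferon-gamma-induced GTPases, interferon-gamma signalling and checkpoint genes, type I interferon-stimulated antiviral genes, nucleic acid sensing, chemokines and inflammatory cytokines, retroelement silencing machinery, KDM5 and H3K4 methylation enzymes, melanocyte differentiation, dedifferentiated and mesenchymal melanoma, AP-1 and immediate early factors, MAPK pathway output and feedback, cell cycle and proliferation, germline and cancer-testis genes, clustered protocadherins, extracellular matrix and adhesion, fibroblast, immune cell, endothelial and keratinocyte markers, and constitutively used promoters. Genes that share a region were counted once. The median and mean of the members and the direction given by camera differed in sign for 9, 8, 5, 1 and 5 lists in the 5 contrasts, 0 of them past the threshold. Whether changed regions lay within 1 kb of a gene end was tested with Fisher's exact test, two-sided, with 95% confidence intervals.

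The named genes follow a rule with 3 parts: Kdm5b; up to 4 members per list past the threshold, by smallest adjusted p, or the member with the highest mean count where none passed; and the 6 largest rises and 6 largest falls among regions past the threshold, at or above the median abundance and with groups that did not overlap, at most 1 per gene. A region was named by the gene with an end within 1 kb, then by the gene it lies in, then by the nearest gene end within 50 kb, and otherwise by position. Of these, 24 genes of the first 2 parts and the 3 largest rises and 3 largest falls were taken per contrast. Taking regions of the last part before the lists were used up departs from the order fixed in advance and was decided after the values had been seen. List members outside this rule were named, where few passed, after their values had been seen.

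The groups, contrasts, tests, gene lists, the rule for named genes and the other settings listed next were chosen before the data were examined. These settings were DESeq2 size factors, library totals alone, trended loess offsets with a span of 0.3, no filter, a term for the replicate number, an absolute log2 fold change of at least 1, the 4 compared libraries alone, each library left out in turn, the Wald test of DESeq2 1.42.0, an offset for copy number, other windows around gene ends, and, for the lists, all regions within 50 kb of a gene end. The copy-number offset removed the median log2 KO against control change of each 10 Mb window with at least 20 regions. Settings without the 12 mitochondrial regions, with all libraries thinned to the smallest total, and with a mean of at least 1 CPM were added after seeing the data, as were the list tests with the copy-number offset, the medians per chromosome and the runs of neighbouring regions. Replicate numbers did not pair the samples: deviations of replicate 1 from replicate 2 correlated between groups, across regions, from -0.105 to 0.152.

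The edgeR test was tested on simulated data with these depths and dispersions and 200 changed regions per contrast, each raised or lowered at random. The changes were placed only in regions with a mean count above 50, so recovery in regions with fewer counts was not measured. The test recovered 30.0% to 60.0% of 2-fold and 80.0% to 98.0% of 4-fold changes. False calls made up 3.79% to 12.0% of all calls, above the nominal share in 4 of the 5 contrasts. In the data 20929 to 38612 regions were called in the first 4 contrasts, far more than the 200 changed here. The adjustment is stricter where fewer regions change, so these shares do not carry over to those contrasts.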

Results

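Accessible chromatin was profiled in YUMMER1.7 melanoma cells with and without Kdm5b, which encodes a demethylase of histone H3 lysine 4, and with and without IFNG, the cytokine that activates STAT1. The 8 libraries, in 4 groups of 2, gave transposase insertion counts over 146899 regions. Control libraries 1 and 2 held 43010015 and 63204255 counts, and control libraries given IFNG held 67138408 and 51118108. KO libraries held 70894182 and 52365668, and KO libraries given IFNG held 113663971 and 129948916. Mitochondrial regions took 6.85% and 5.66% of the counts in control cells given IFNG, 2.18% and 2.77% in untreated control cells, 0.974% and 1.20% in KO cells, and 1.61% and 0.591% in KO cells given IFNG. Every group below has n = 2 libraries, fold changes are log2 values ± SE, and positions are in mm10. In each of the first 4 contrasts the groups did not overlap for the 23 named list members past the threshold. These members were chosen by adjusted p, so this adds no support. The chance rate of 33.3% holds only for genes not chosen by p-value. The largest rises and falls were taken only from regions whose groups did not overlap.

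The gene-end region of Kdm5b itself (chromosome 1, 134560011 to 134561241) stayed accessible in the KO cells. It held 17.8 and 20.4 CPM (counts scaled to a common library total) in the control libraries, 14.1 and 16.3 CPM with IFNG, 13.6 and 17.0 CPM in the KO libraries, and 16.8 and 17.65 CPM in KO cells given IFNG. No contrast passed the threshold at this region with TMM scaling and all 8 libraries. It passed for untreated KO against control without KO replicate 2 (-0.49) and for KO against control given IFNG with library totals alone (0.41). It also passed for IFNG in control cells with library totals alone (-0.51) and with loess offsets (-0.42). The KO against control fold change was -0.32 ± 0.14 without IFNG (adjusted p = 0.0932) and 0.19 ± 0.14 with IFNG (adjusted p = 0.388). The IFNG response of Kdm5b was -0.33 ± 0.14 in control and 0.18 ± 0.14 in KO cells (adjusted p = 0.118 and 0.373), and the difference of these was 0.51 ± 0.20 (adjusted p = 0.285). Of the other regions in or near Kdm5b, named after their values were seen, that at 134573118 was lower in untreated KO cells (-0.90 ± 0.32, adjusted p = 0.0374) and that at 134617768 was higher (1.01 ± 0.29, adjusted p = 0.00926). Neither passed with IFNG (-0.20 and 0.43, adjusted p = 0.709 and 0.337). That at 134636743 was higher in KO cells given IFNG (0.97 ± 0.33, adjusted p = 0.0317) and did not pass without it (adjusted p = 0.0825). With IFNG the region at 134583431 fell in control and KO cells (-0.70 and -0.55, adjusted p = 0.00858 and 0.0201), and that at 134617768 fell in KO cells (-1.10 ± 0.27, adjusted p = 0.00289). These counts do not show whether the deletion is present.

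**Figure D1:**
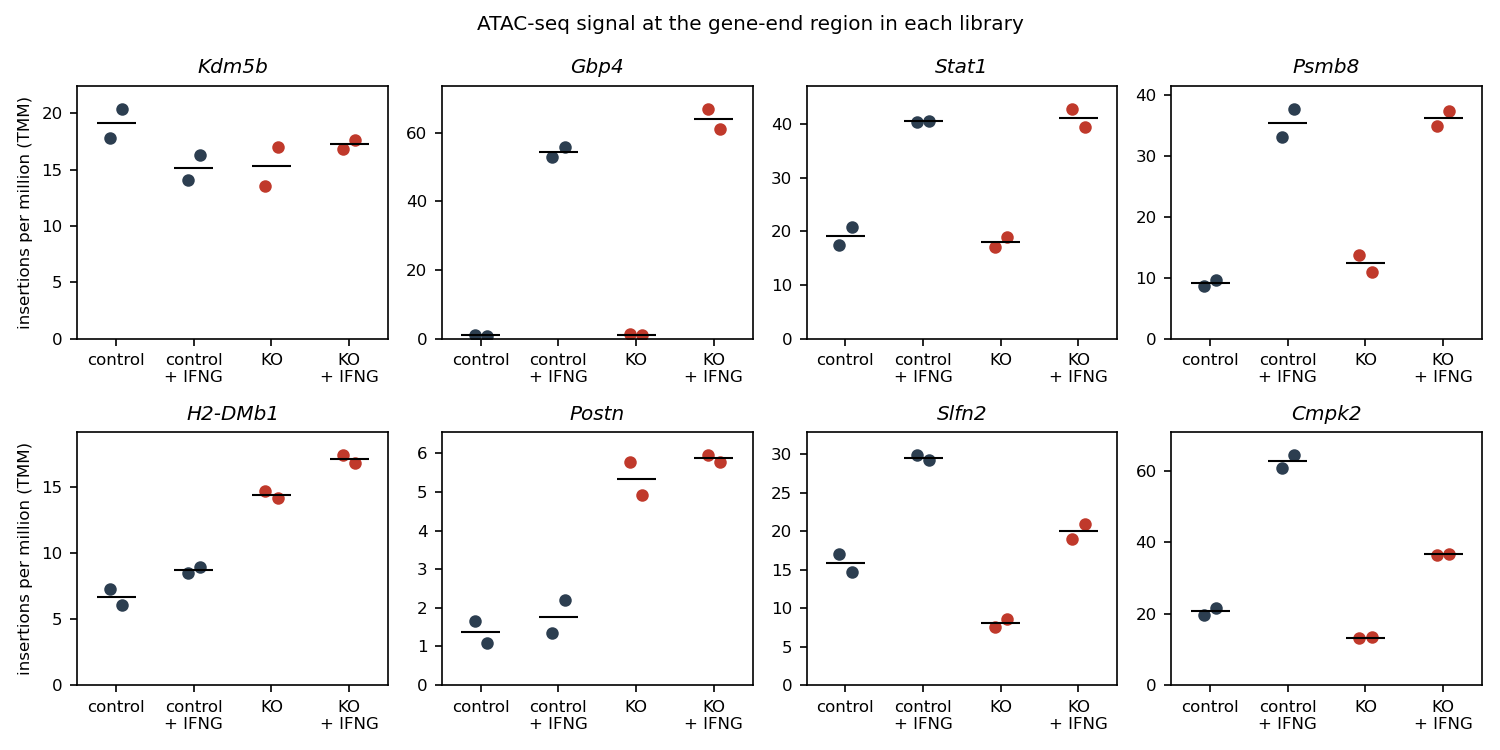
Transposase insertions in TMM-scaled CPM (vertical axis) at the gene-end region of 8 genes in the 4 groups, with 1 point per library and a line at the mean of 2 libraries, without error bars. Gbp4, Stat1, Psmb8 and Cmpk2 were higher with IFNG in both genotypes, Postn and H2-DMb1 were higher in KO cells with and without IFNG, and Kdm5b passed no test with TMM scaling and all libraries.

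Without IFNG, the comparison of KO with control cells asks what loss of KDM5B did to accessible chromatin at rest. Rab38, which acts in melanosome transport, rose most among the listed genes, by 3.73 ± 0.43 (13.3-fold) at chromosome 7, 88430082 to 88430447 (adjusted p = 9.41e-08). Postn, which encodes the matrix protein periostin, rose by 1.98 ± 0.24 (adjusted p = 2.71e-07), and the microfibril gene Mfap5 rose by 1.96 ± 0.30 (adjusted p = 9.22e-06). Of the named genes that were lower in KO cells, Slfn2 changed by -0.98 ± 0.14 (adjusted p = 3.37e-06), Rsad2, which encodes the antiviral protein viperin, by -0.92 ± 0.18 (adjusted p = 0.000458), Cmpk2 by -0.65 ± 0.13 (adjusted p = 0.000291) and Sting1, the adaptor of cytosolic DNA sensing, by -0.87 ± 0.18 (adjusted p = 0.000621).

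Over all regions, 18280 were higher and 17967 lower in untreated KO cells, of which 12085 and 5507 differed at least 2-fold. Among the regions at or above the median abundance, the 3 largest rises lay at chromosome 12, 118569776 to 118570277, more than 50 kb from an end of any protein-coding gene, in Fam13c (5.11 ± 0.40, adjusted p = 2.38e-10) and in Rarb, a retinoic acid receptor gene (4.73 ± 0.27, adjusted p = 1.37e-14). The first of these rose by 5.39 ± 0.34 (adjusted p = 1.3e-13). The 3 largest falls lay in Arhgap28 (-4.50 ± 0.33, adjusted p = 7.73e-12), in Camta1 (-3.22 ± 0.23, adjusted p = 6.32e-12) and at chromosome 6, 51715248 to 51715786 (-2.71 ± 0.29, adjusted p = 2.17e-08).

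The MHC class II, fibroblast and immune cell lists leaned upward in untreated KO cells. Of 10 measured MHC class II genes, 2 rose and none fell (camera adjusted p = 0.00938): H2-Ab1, and H2-DMb1 by 1.12 ± 0.15 (adjusted p = 1.42e-06). Of 11 fibroblast markers 4 rose (Acta2, Dpt, Mfap5 and Rgs5) and 1, Cd34, fell (camera adjusted p = 0.00526). Of 9 immune cell markers 3 rose and 1, Cd4, fell (camera adjusted p = 0.0279). Those that rose were Gzmb and the myeloid genes Lyz2 (1.62 ± 0.25, adjusted p = 1.28e-05) and S100a8 (1.12 ± 0.19, adjusted p = 3.06e-05). For each of these 3 lists the call was lost, with adjusted p = 0.291 with an estimated correlation, and the same counts were found adjusted over the list alone. With the copy-number offset 1 MHC class II gene rose and 0 fell, 3 fibroblast markers rose and 1 fell, and 3 immune cell markers rose and 0 fell.

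No other list passed the test in untreated KO cells, with adjusted p from 0.0524 to 0.865. With the copy-number offset the MAPK output list passed downward (adjusted p = 0.0494) and the clustered protocadherins passed upward (adjusted p = 2.18e-06), neither with an estimated correlation (adjusted p = 0.970 and 0.0915). With all regions within 50 kb the MAPK output list (adjusted p = 0.000638) and the silencing list (adjusted p = 0.0439) passed downward. That setting also lost 10 of the 23 list calls made over all contrasts. Of the MAPK output list, 6 of 24 members fell and none rose, including Spry4, a feedback inhibitor of the pathway (-0.80 ± 0.14, adjusted p = 7.53e-05), and the transcription factor gene Etv1 (-0.85 ± 0.16, adjusted p = 0.000308). Of 34 dedifferentiated melanoma genes 8 fell, including Twist1 (-0.72 ± 0.13, adjusted p = 8.9e-05) and the cadherin gene Cdh2 (-0.69 ± 0.14, adjusted p = 0.00028), and 1, Lox, rose. Of 27 retroelement silencing genes 6 fell, including Atrx (-0.87 ± 0.15, adjusted p = 4.23e-05) and Cbx3 (-0.60 ± 0.13, adjusted p = 0.000745), and 1, Atf7ip2, rose. Cdkn1a, which encodes the cell-cycle inhibitor p21, rose by 0.99 ± 0.20 (adjusted p = 0.000331), while Cdkn1b changed by -0.65 ± 0.14 (adjusted p = 0.000687). The counts for the MAPK, melanoma and silencing lists were the same adjusted over the list alone. With the copy-number offset 6, 5 and 3 members of these lists fell and 0, 1 and 0 rose. Falls outnumbered rises among all 19394 regions within 1 kb of a gene end, with 2277 lower and 904 higher. The constitutively used promoters had a median of -0.22, against -0.23, -0.16 and -0.15 for these lists. Over all regions within 50 kb the median of those promoters was -0.21, against -0.12 for the silencing list.

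In the remaining lists of untreated KO cells, members went both ways or few passed. Of 17 GTPases 3 were higher (Gbp8, Gvin1 and Ifi47) and 3 lower (Gbp2, Gbp9 and Tgtp2), and of 21 MHC class I genes 2 were higher (H2-Q7 and Psmb8) and 2 lower (Erap1 and Tapbpl). Of 35 type I interferon genes 2 were higher (Slfn8 and the region shared by Parp9 and Dtx3l) and 5 lower (Cmpk2, Herc6, Rsad2, Slfn2 and Usp18). Ptpn2 alone was lower of 23 IFNG signalling genes, Sting1 alone of 25 nucleic acid sensors and Ccl20 alone of 18 chemokines. Of 16 melanocyte genes 3 were higher (Plp1, Rab27a and Rab38) and 2 lower (Met and Tfap2b). In the list of KDM5 and H3K4 methylation enzymes, which also holds demethylases such as Kdm5b, 2 of 16 genes were lower (Kdm1b and Kdm5a). Of 5 endothelial markers Cdh5 was higher, and of 8 keratinocyte markers 2 were higher (Krt14 and Lor) and 3 lower (Dsc3, Itga6 and Krt1). All of these counts were the same adjusted over the list alone. With the copy-number offset 0 members passed in the IFNG signalling, nucleic acid sensor, KDM5 and endothelial lists. The offset left 1 type I interferon gene higher and 3 lower, 2 GTPases higher and 3 lower, and 2 keratinocyte markers each way. It left 3 melanocyte genes higher and 1 lower, while the counts for MHC class I genes and chemokines stayed the same.

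Of 24 AP-1 genes 4 were lower in untreated KO cells (Egr1, Fos, Klf6 and Myc), or 3 adjusted over the list alone. Of 34 cell-cycle genes 1 was higher (Cdkn1a) and 3 lower (Ccne2, Cdkn1b and Mcm2), of which 2 were lower adjusted over the list alone. Of 13 germline genes 1 was higher (Stag3) and 2 lower (Naa11 and Tex11), of which 1 was lower adjusted over the list alone. Of 33 matrix genes 3 were higher (Mmp14, Mmp2 and Postn) and 3 lower (Col4a1, Itga6 and Lamb1), of which 0 were lower adjusted over the list alone. Of 24 constitutively used promoters 4 were lower (Hnrnpk, Ppia, Sdha and Ubc), or 2 adjusted over the list alone. Of 23 clustered protocadherin regions 2 were higher (Pcdhb12 and Pcdhb3) and 6 lower, the same adjusted over the list alone, and this turned to 7 higher and 1 lower with the copy-number offset.

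The call was lost with the copy-number offset for 8 of 29 named genes in untreated cells, which were Spry4, Twist1, Pcdhgc5, Etv1, Met, Sting1, Cdkn1b and Cbx3. It was kept but the fold change shrank over 1.5 times for Pcdhga1 (-1.12 to -0.69), Cmpk2 (-0.65 to -0.36) and Tapbpl (-0.70 to -0.40). The total was 36247 changed regions, but 21883 without KO replicate 1 and 22142 without control replicate 2. The share that was higher was 50.4%, against 47.1% with the DESeq2 Wald test and 68.0% with library totals alone, where the median of all regions was 0.14.

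With IFNG, the comparison of KO with control cells asks whether the same regions differed once the cytokine was present. Postn again rose, by 1.74 ± 0.23 (3.34-fold, adjusted p = 1.71e-06), as did S100a8 by 1.23 ± 0.18 (adjusted p = 5.33e-06), Rab38 by 2.48 ± 0.42 (adjusted p = 5.34e-05) and Cdkn1a by 1.11 ± 0.20 (adjusted p = 0.000104). Cmpk2 was again lower, at -0.77 ± 0.12 (adjusted p = 2.06e-05), and so was Slfn2, at -0.57 ± 0.13 (adjusted p = 0.00222). Hbegf, which encodes a ligand of the EGF receptor, was lower at -0.83 ± 0.13 (adjusted p = 1.66e-05), and the basement membrane collagen gene Col4a1 was lower at -1.66 ± 0.38 (adjusted p = 0.00157).

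In all, 16744 regions were higher and 14460 lower in KO cells given IFNG, of which 11017 and 3786 differed at least 2-fold. The 3 largest rises were in Rarb (4.14 ± 0.28, adjusted p = 1.5e-12), near Rit2 (4.08 ± 0.36, adjusted p = 1.18e-09) and at chromosome 9, 93131375 to 93132309 (4.04 ± 0.26, adjusted p = 2.45e-13). The 3 largest falls were in Arhgap28 (-4.70 ± 0.30, adjusted p = 2.96e-13), at an end of Arhgef3 (-3.54 ± 0.30, adjusted p = 2.51e-10) and in Uggt2 (-3.26 ± 0.24, adjusted p = 1.47e-11).

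MHC class II genes and fibroblast markers passed the list test again in cells given IFNG. Of 10 MHC class II genes 5 rose (H2-Aa, H2-Ab1, H2-DMb1, H2-Eb1 and Ifi30) and none fell (6 adjusted over the list alone), with H2-DMb1 at 0.98 ± 0.15 (adjusted p = 1.07e-05) and H2-Ab1 at 0.81 ± 0.20 (adjusted p = 0.00261). Of 11 fibroblast markers 4 rose and none fell (5 adjusted over the list alone), which were Fap, Myh11, Dpt (1.26 ± 0.23, adjusted p = 0.000114) and Mfap5 (1.39 ± 0.31, adjusted p = 0.00116). The camera adjusted p was 0.000672 and 3.38e-05, and for both lists it was adjusted p = 0.191 with an estimated correlation. The other 20 lists had adjusted p from 0.130 to 0.977. With the copy-number offset the clustered protocadherins (adjusted p = 0.00454) and the matrix genes (adjusted p = 0.0376) passed upward, neither with an estimated correlation (adjusted p = 0.142 and 0.944). With all regions within 50 kb the MAPK output list (adjusted p = 0.000921), the AP-1 genes (adjusted p = 0.0149) and the keratinocyte markers (adjusted p = 0.0168) passed downward. Over all contrasts 10 of the 23 list calls were lost under that setting. Without the offset 5 protocadherins were lower with IFNG (Pcdha6, Pcdhga1, Pcdhga3, Pcdhgc3 and Pcdhgc5) and none higher, the same adjusted over the list alone, against 3 higher and 1 lower with it. In the silencing list 4 of 27 members were lower (Atf7ip, Atrx, Cbx3 and Trim24) and none higher, the same adjusted over the list alone, with Atrx at -0.78 ± 0.15 (adjusted p = 0.000173) and Atf7ip at -0.64 ± 0.14 (adjusted p = 0.000759). With the copy-number offset 2 members of this list were lower and 0 higher. Among all regions within 1 kb of a gene end 1783 were lower and 804 higher.

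In cells given IFNG the call was lost with the copy-number offset for Pcdhga3, Atf7ip, Tgfbi, Pcdhgc3 and Spry1, and with library totals alone for Slfn2 (adjusted p = 0.051). With the offset the call was kept but the fold change shrank over 1.5 times for Hbegf (-0.83 to -0.43), Cmpk2 (-0.77 to -0.43) and Pcdhga1 (-1.01 to -0.61). It was lost without control_IFNG replicate 1 for Tgfbi (adjusted p = 0.0511), Lyz2 (adjusted p = 0.0914) and H2-Ab1 (adjusted p = 0.0944). Without control_IFNG replicate 2 it was lost for Pcdhgc3 (adjusted p = 0.0689), Spry1 (adjusted p = 0.0596), Tlr7 (adjusted p = 0.0614) and Fap (adjusted p = 0.0944). Without KO_IFNG replicate 1 it was lost for Tgfbi (adjusted p = 0.0571), Spry1 (adjusted p = 0.0593), Slfn2 (adjusted p = 0.0566) and Fap (adjusted p = 0.0998). The total was 31204 changed regions, but 14281 without KO_IFNG replicate 1 and 13775 and 15428 without control_IFNG replicates 1 and 2. The share that was higher was 53.7%, against 48.8% with the DESeq2 Wald test and 83.4% with library totals alone, where the median of all regions was 0.25 in place of 0.02.

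Regions that differed between KO and control cells overlapped between the untreated and the IFNG libraries, which have no library in common. Of the higher regions 8814 were shared, where independent lists of these sizes would share 2084, and of the lower regions 8239 were shared, where independent lists would share 1769. Across regions, which are not independent replicates, the pair of fold changes correlated with r = 0.655.

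Differences between KO and control cells also ran along whole chromosomes. The median fold change of all regions on chromosome 16 was 0.39 without and 0.41 with IFNG, and 90.7% and 93.1% of its changed regions were higher in KO cells. Chromosome 18, which holds the clustered protocadherins, Spry4 and Sting1, had medians of -0.35 and -0.31, and chromosome 6, which holds Met, Cdkn1b and Cbx3, had -0.31 and -0.25. Over 273 windows of 10 Mb, 38 medians without and 48 with IFNG lay beyond 0.3 in either direction, and the window medians of the pair correlated with r = 0.918 across windows, which are not independent replicates. For the IFNG responses only 1 window in control and 2 in KO cells lay beyond 0.3.

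**Figure D2:**
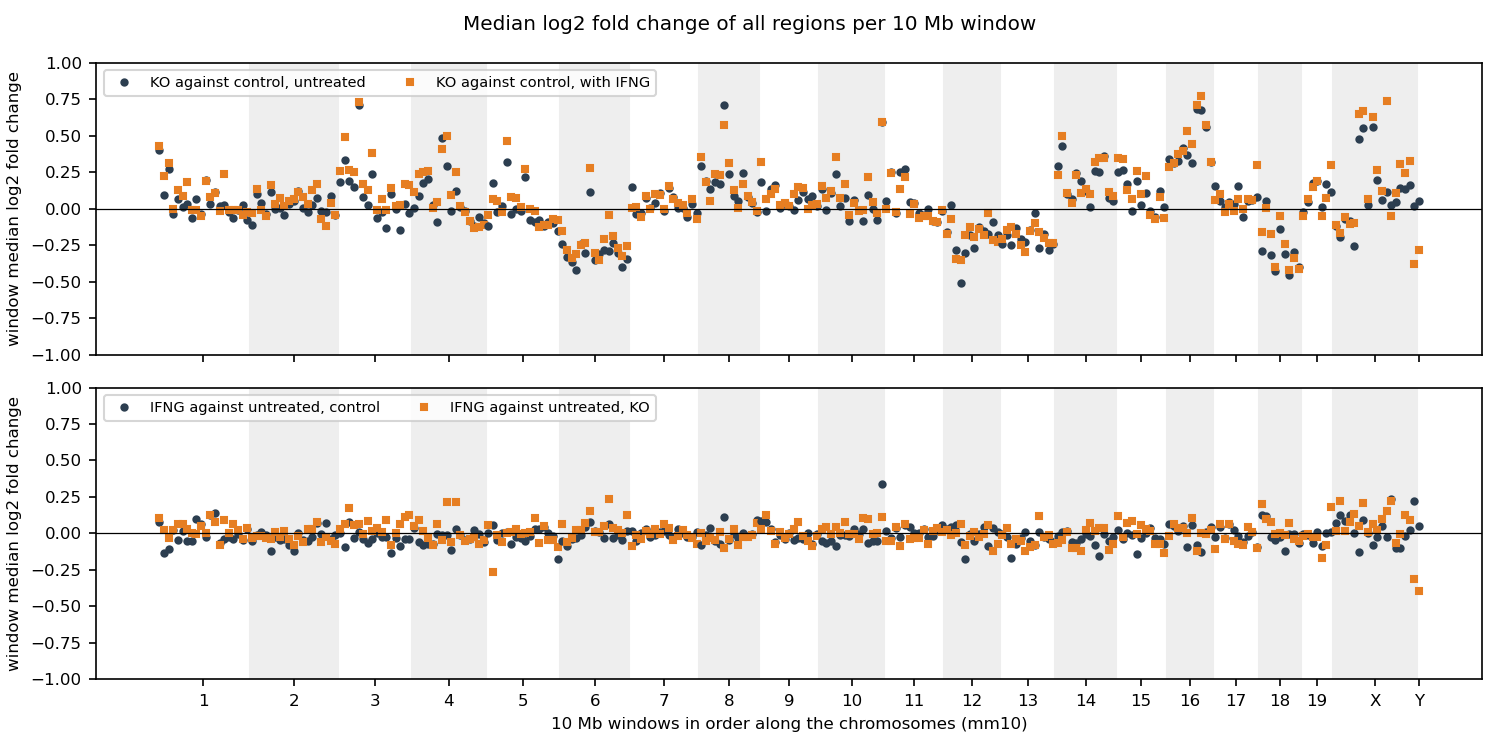
Median log2 fold change of all regions (vertical axis) in 273 windows of 10 Mb in order along the chromosomes (horizontal axis), for KO against control in the upper panel and IFNG against untreated in the lower panel, with 1 point per window and contrast. Chromosome 16 lay above 0 and chromosomes 6 and 18 lay largely below 0 for KO against control with and without IFNG, while the windows stayed near 0 for IFNG against untreated.

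The IFNG response in control cells shows which regions opened with the cytokine in cells with intact Kdm5b. The gene-end region of Gbp4, a guanylate-binding GTPase of cell-autonomous immunity, went from 0.912 ± 0.285 to 54.4 ± 2.16 CPM (mean ± SD), a rise of 5.93 ± 0.18 (60.9-fold, adjusted p = 1.14e-22) at chromosome 5, 105113715 to 105116174. All 17 GTPase genes rose, also adjusted over the list alone, with a median of 2.48, among them Tgtp1 (5.08 ± 0.20, adjusted p = 1.39e-19), Tgtp2 (3.97 ± 0.16, adjusted p = 1.39e-19) and Irgm2 (2.54 ± 0.14, adjusted p = 1.04e-15). Of 35 type I interferon genes 26 rose (29 adjusted over the list alone), such as Ifit3 (2.57 ± 0.13, adjusted p = 6.25e-17) and Oasl2 (2.13 ± 0.17, adjusted p = 6.02e-12), and 1, Rtp4, fell by 0.57 ± 0.18 (adjusted p = 0.0248).

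Genes of MHC class I antigen presentation also rose in control cells. Of 10 MHC class II genes 2 rose (Cd74 and H2-DMa), the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.259) unless all regions within 50 kb were taken (adjusted p = 0.0160). Of 21 MHC class I genes 15 rose and none fell (19 adjusted over the list alone), with a median of 0.67. They included Nlrc5, the transactivator of MHC class I genes (2.05 ± 0.14, adjusted p = 1.43e-13), the immunoproteasome gene Psmb8 (1.96 ± 0.14, adjusted p = 8.56e-13) and H2-K1 (1.39 ± 0.14, adjusted p = 2.76e-09). Of 23 IFNG signalling genes 11 rose (12 adjusted over the list alone), including Batf2 (3.77 ± 0.16, adjusted p = 3.28e-19), Stat1 (1.08 ± 0.13, adjusted p = 1.41e-07) and Irf9 (1.03 ± 0.13, adjusted p = 3.63e-07). Of 25 nucleic acid sensors 8 rose, and adjusted over the list alone 8 rose and 1 fell, with Zbp1 at 3.63 ± 0.15 (adjusted p = 2.93e-19). Of 18 chemokine and cytokine genes 6 rose (8 adjusted over the list alone), such as Tnfsf10, which encodes the death ligand TRAIL (1.54 ± 0.17, adjusted p = 9.6e-09), and Cxcl10 (1.02 ± 0.14, adjusted p = 2.1e-06).

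Camera in control cells gave an adjusted p of 9.25e-187 for the GTPases and 8.97e-59 for the type I interferon genes, and both calls held with an estimated correlation (adjusted p = 0.00114 for both). The MHC class I list had 2.27e-29, the IFNG signalling list 2.61e-13, the sensors 1.82e-08, the chemokines 0.000251 and the constitutively used promoters, with 1 of 24 members higher and 0 adjusted over the list alone, 0.0388. For these lists, in the same order, adjusted p = 0.0721, 0.143, 0.189, 0.0721 and 0.977 with an estimated correlation. The other 15 lists had adjusted p from 0.122 to 0.919, and of these the fibroblast markers passed downward with all regions within 50 kb (adjusted p = 0.0436). Over all contrasts 10 of the 23 list calls were lost with all regions within 50 kb. The cancer-testis gene Rhox5 rose by 1.16 ± 0.19 (adjusted p = 3.33e-05), and by 0.60 ± 0.19 in KO cells (adjusted p = 0.0151).

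In control cells 14664 regions rose and 6265 fell with IFNG, of which 7643 and 2465 changed at least 2-fold. The 3 largest rises were a further region of Gbp4 (6.07 ± 0.43, adjusted p = 4.26e-13), Gm12250 (5.77 ± 0.23, adjusted p = 7.65e-19) and Iigp1 (5.68 ± 0.39, adjusted p = 8.54e-06). The 3 largest falls lay in Tpk1 (-2.31 ± 0.41, adjusted p = 0.0014, but adjusted p = 0.0516 without control_IFNG replicate 1), in Nedd9 (-2.15 ± 0.30, adjusted p = 1.85e-06) and at chromosome 9, 34204421 to 34205037 (-2.08 ± 0.35, adjusted p = 0.000397). The total of 20929 was 12084 without control replicate 2, and 9523 and 10709 without control_IFNG replicates 1 and 2. With library totals alone, 9505 regions rose and 16369 fell in control cells, and the median of all regions was -0.19 in place of -0.01, so the share that rose was 36.7% in place of 70.1%.

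The IFNG response in KO cells shows which regions opened with the cytokine in cells with Kdm5b knocked out. Gbp4 rose by 5.78 ± 0.17 (55.1-fold, adjusted p = 4.6e-23), from 1.16 ± 0.0915 to 64.1 ± 4.03 CPM (mean ± SD). All 17 GTPase genes rose, also adjusted over the list alone, with a median of 2.49, including Tgtp1 (4.49 ± 0.19, adjusted p = 5.06e-19) and Gbp10 (4.83 ± 0.24, adjusted p = 2.65e-17). Of 35 type I interferon genes 29 rose and none fell, the same adjusted over the list alone, such as Ifit3b (2.44 ± 0.13, adjusted p = 1.34e-16) and Oasl2 (1.89 ± 0.16, adjusted p = 3.9e-11).

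Of 21 MHC class I genes 18 rose in KO cells, the same adjusted over the list alone, with a median of 0.66, including Nlrc5 (1.66 ± 0.14, adjusted p = 1.11e-11), Psmb8 (1.55 ± 0.14, adjusted p = 9.56e-11) and Tapbpl (1.12 ± 0.14, adjusted p = 1.26e-07). Of 23 IFNG signalling genes 12 rose, and adjusted over the list alone 12 rose and 2 fell, with Batf2 at 3.82 ± 0.16 (adjusted p = 2.82e-19), Stat1 at 1.19 ± 0.13 (adjusted p = 8.75e-09) and the inflammatory caspase gene Casp4 at 1.12 ± 0.16 (adjusted p = 1.16e-06). Of 25 nucleic acid sensors 10 rose (11 adjusted over the list alone), such as Zbp1 (3.33 ± 0.15, adjusted p = 1.06e-18) and Samhd1 (0.76 ± 0.13, adjusted p = 2.23e-05). Of 18 chemokine genes 6 rose and 2, Cxcl1 and Cxcl12, fell (9 and 2 adjusted over the list alone), with Tnfsf10 at 1.27 ± 0.16 (adjusted p = 1.45e-07). Ngfr, a marker of neural-crest-like melanoma cells, rose by 1.96 ± 0.23 (adjusted p = 1.14e-06), and also rose in control cells (1.27 ± 0.23, adjusted p = 0.000508). The fibroblast marker Dpt rose by 1.20 ± 0.22 (adjusted p = 8.98e-05), against 0.62 ± 0.25 in control cells (adjusted p = 0.0912). The difference of the responses was not called for Ngfr (adjusted p = 0.398) or Dpt (adjusted p = 0.507).

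Clustered protocadherins fell as a list in KO cells given IFNG, with 4 of 23 members lower (Pcdhac1, Pcdhb15, Pcdhb17 and Pcdhb6) and none higher (3 lower adjusted over the list alone, camera adjusted p = 0.00514), as did keratinocyte markers, with 3 of 8 lower (Lor, Pkp1 and Sfn), the same adjusted over the list alone (camera adjusted p = 0.0422). These calls were lost, with adjusted p = 0.117 and adjusted p = 0.191 with an estimated correlation. Camera gave 1.96e-164 for the GTPases and 1.80e-50 for the type I interferon genes in KO cells, and both held with an estimated correlation (adjusted p = 0.00234 and 0.00210). The MHC class I list had 2.10e-21, the IFNG signalling list 1.03e-13, the sensors 1.47e-08, the chemokines 0.00476 and the constitutively used promoters, with 2 of 24 members higher and 1 adjusted over the list alone, 0.0288. For these lists, in the same order, adjusted p = 0.117, 0.117, 0.161, 0.117 and 0.899 with an estimated correlation. The other 13 lists had adjusted p from 0.0579 to 0.865.

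In KO cells 23828 regions rose and 14784 fell with IFNG, of which 12534 and 6007 changed at least 2-fold. The 3 largest rises were a further region of Gbp4 (6.57 ± 0.42, adjusted p = 2.39e-14), Iigp1 (6.33 ± 0.41, adjusted p = 3.53e-06) and a region beside Irf1 (5.54 ± 0.20, adjusted p = 4.05e-19). The 3 largest falls lay in Prtg (-2.62 ± 0.21, adjusted p = 1.18e-11), near Adrb3 (-2.43 ± 0.19, adjusted p = 2.73e-12) and in Tpk1 (-2.40 ± 0.38, adjusted p = 0.00027). The total of 38612 was 25358 without KO replicate 1 and 23152 without KO_IFNG replicate 1. With library totals alone 50.3% of the changed regions rose in KO cells, in place of 61.7%, with the median of all regions at -0.08.

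Regions that changed with IFNG were shared between the genotypes, which have no library in common. Of the regions that rose in control cells 10866, or 74.1%, also rose in KO cells, where independent lists would share 2379. Of those that fell in control cells 2642, or 42.2%, also fell in KO cells, where independent lists would share 631. The fold changes correlated with r = 0.692 across regions, which are not independent replicates.

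**Figure D3:**
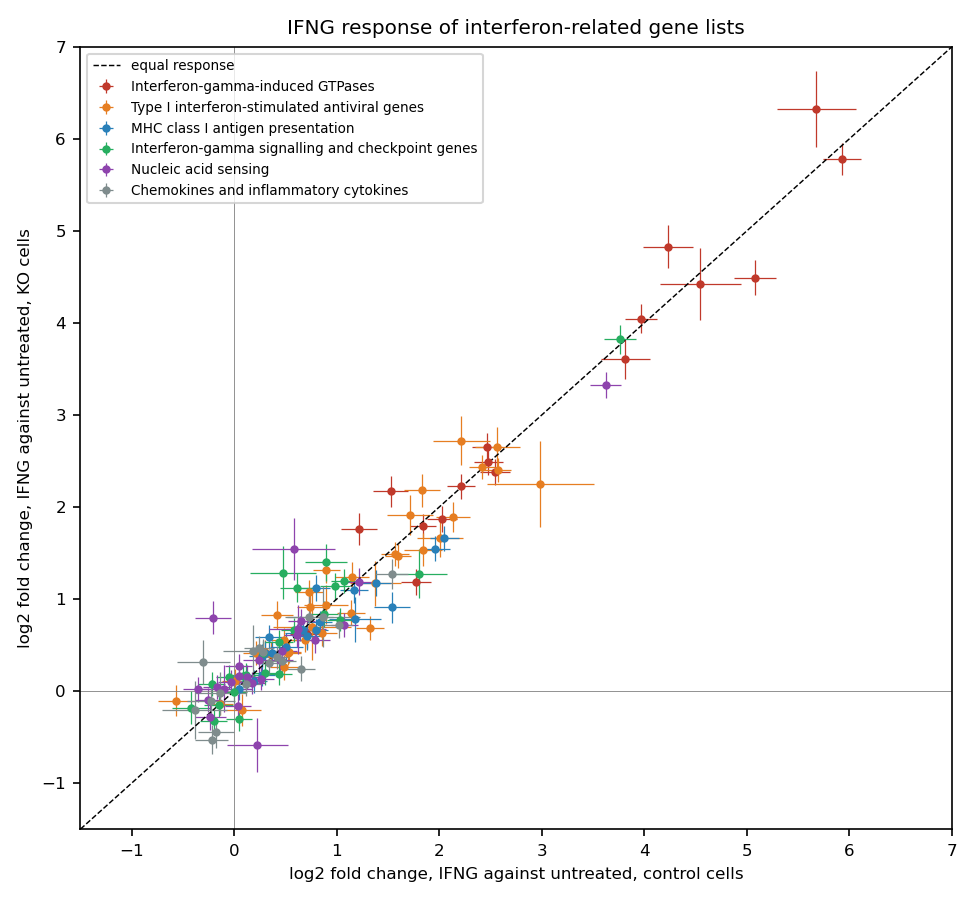
Log2 fold change with IFNG in control cells (horizontal axis) against KO cells (vertical axis) at the gene-end regions of 6 interferon-related gene lists, with 1 point per gene and bars for the SE of the edgeR fit. The points lie along the dashed line of equal response, with the GTPases highest at medians of 2.48 in control and 2.49 in KO cells.

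The difference of the IFNG responses asks whether KO cells responded to the cytokine unlike control cells. It was found at 781 regions, 618 with a higher and 163 with a lower response in KO cells, and no gene-end region of any of the 22 gene lists was among them. Higher means a positive signed difference, from a larger rise or a smaller fall in KO cells. Of 446 regions of list members 0 passed with edgeR and 0 with DESeq2, and 38 had an unadjusted edgeR p under 0.05. Calls were few at gene ends in general, with 20 higher and 5 lower of 19394 regions within 1 kb. Over all 146899 regions 17225 had an unadjusted edgeR p under 0.05. DESeq2 gave no adjusted p for 48417 regions of this contrast, which counted as not passed. In the simulation 2% of 1.5-fold and 30% of 2-fold differences were recovered, so the 0 does not show equal responses. Of all regions within 50 kb of list genes some were called. There were 1 higher and 2 lower of 143 for the GTPases, 3 and 1 of 189 for chemokines and 3 and 1 of 495 for matrix genes. There were 2 and 1 of 219 for AP-1 genes, and 1 and 2 of 435 for dedifferentiated melanoma genes. There were 2 higher of 128 for nucleic acid sensors and 2 of 49 for germline genes. The MAPK genes had 1 higher and 1 lower of 289, and there was 1 higher of 231 for cell-cycle genes and 1 of 45 for endothelial markers. Single members passed adjusted over the list alone in 3 lists: 1 nucleic acid sensor with a higher response in KO cells, Sting1 (1.00 ± 0.25, adjusted p = 0.0558 over all regions), 1 AP-1 gene with a lower response, Junb (-0.65 ± 0.19, adjusted p = 0.107 over all regions), and 1 immune marker with a lower response, Gzmb (-1.22 ± 0.37, adjusted p = 0.127 over all regions). The responses of Sting1 were -0.21 ± 0.18 in control cells (adjusted p = 0.482) and 0.80 ± 0.18 in KO cells (adjusted p = 0.00102), and all 3 genes were named after their values were seen. For Ifit3b the difference was 0.02 ± 0.17 (adjusted p = 0.98), for the GTPase gene Irgm1 0.02 ± 0.19 (adjusted p = 0.985), for Socs1, a feedback inhibitor of interferon signalling, 0.08 ± 0.19 (adjusted p = 0.914) and for the proteasome activator gene Psme2 0.11 ± 0.18 (adjusted p = 0.858).

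The 3 largest positive differences lay at chromosome 10, 46665263 to 46665999 (3.14 ± 0.40, adjusted p = 0.000248), at chromosome 10, 97297760 to 97298368 (2.98 ± 0.36, adjusted p = 4.81e-05) and 13687 bp from an end of Ptgfr, a prostaglandin receptor gene (2.55 ± 0.44, adjusted p = 0.00442). The 3 largest negative differences lay at chromosome 1, 47398576 to 47399362 (-2.05 ± 0.23, adjusted p = 2.4e-05), near Tmcc3 (-2.04 ± 0.42, adjusted p = 0.0221) and at chromosome 8, 4433035 to 4433712 (-1.99 ± 0.41, adjusted p = 0.0147). Without control_IFNG replicate 2 the calls were lost at Ptgfr (adjusted p = 0.0672), Tmcc3 (adjusted p = 0.118) and 4433035 (adjusted p = 0.0597). Those at Tmcc3 and 4433035 were also lost without control_IFNG replicate 1 (adjusted p = 0.114 and 0.0941) and without control replicate 2 (adjusted p = 0.135 and 0.185), and that at Tmcc3 without KO replicate 1 (adjusted p = 0.106) and without KO_IFNG replicate 1 (adjusted p = 0.106).

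As lists, MAPK output genes leaned toward a higher response in KO cells (camera adjusted p = 0.0238) and keratinocyte markers toward a lower one (camera adjusted p = 0.0311), with 0 of 24 and 0 of 8 members past the threshold, also adjusted over the list alone. Both calls were lost, with adjusted p = 0.985 and adjusted p = 0.655 with an estimated correlation. The other 20 lists had adjusted p from 0.0767 to 0.981, and of these the clustered protocadherins passed downward with library totals alone (adjusted p = 0.0169). The count of 781 and its direction rested on single libraries. It was 362 without KO replicate 1, 142 and 2049 without KO_IFNG replicates 1 and 2, 269 without control replicate 2, and 131 and 74 without control_IFNG replicates 1 and 2, and without control replicate 1 41.6% of 1003 regions were higher in place of 79.1%. With library totals alone 91.1% were higher, with the median of all regions at 0.11 in place of 0.01.

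Because KDM5B acts on a histone mark of promoters, the place of the changed regions was compared with that of all others. Strand was not available, so a gene end is either end of a gene and not a promoter alone. Regions higher in KO cells were scarce at gene ends: 4.95% of those found without IFNG lay within 1 kb of a gene end, against 14.4% of the other regions (odds ratio 0.310, 95% confidence interval 0.289 to 0.332), and the odds ratio was 0.303 (0.281 to 0.326) with IFNG. Regions that rose with IFNG were also scarce there, with odds ratios of 0.412 (0.384 to 0.441) in control and 0.379 (0.359 to 0.401) in KO cells. Regions that fell with IFNG had odds ratios of 1.15 (1.07 to 1.24) in control and 0.848 (0.804 to 0.894) in KO cells. Regions lower in KO cells lay near an even share, at 0.948 (0.904 to 0.994) without IFNG, which turned to 1.00 with a window of 500 bp, and 0.917 (0.870 to 0.966) with IFNG. For the difference of the responses the odds ratios were 0.219 (0.133 to 0.342) for higher and 0.208 (0.0666 to 0.495) for lower regions. These intervals count regions, which are not independent replicates, and do not measure the spread between libraries. The odds ratios were computed again with other windows only, not with other scaling of the libraries.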

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

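The thinning of libraries and the removal of mitochondrial regions were tests chosen after the counts had been seen, while the copy-number offset was planned. The test of the difference between the IFNG responses of KO and control cells passed at 781 regions. The single regions named from it had differences of 3.14 (chromosome 10, 46665263), 2.98 (chromosome 10, 97297760) and 2.55 (near Ptgfr) on the positive side. On the negative side they were -2.05 (chromosome 1, 47398576), -2.04 (near Tmcc3) and -1.99 (chromosome 8, 4433035). The list test of the same difference passed for MAPK pathway genes (adjusted p = 0.0238) and for keratinocyte markers (adjusted p = 0.0311), without a member past the threshold in either, and both calls were lost with an estimated correlation (adjusted p = 0.985 and 0.655).

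The difference, KO response minus control response, was positive at 618 of the 781 regions. A larger rise or a smaller fall in KO cells gives a positive value, and these were not told apart. KO cells given IFNG had the deepest libraries, while control cells given IFNG had the most mitochondrial counts. After all libraries were thinned to the smallest total, 77.7% of 815 regions were higher, above the 70% set as the bound against depth of the counts as the cause. Mitochondrial counts had next to no part in the TMM scaling, as leaving them out moved that of no library by more than 0.00881%, which argues against the scaling as their route, while the same 781 calls (79.1% higher) add nothing to this. The merged peak set may favour regions open in the deepest libraries, which was not tested, and the share fell to 41.6% without control replicate 1 and 56.3% without KO_IFNG replicate 1. A difference in the response of cells without KDM5B stays open beside a deviation of single libraries. A response particular to the KO clone stays open too, since the KO group is not known to hold more than 1 clone.

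Untreated KO and control cells differed at 36247 regions. After thinning the number was 93.9% of this, and 89.6% of the same regions kept their call and direction. This argues against the depth of the counts as the cause. The totals of untreated KO and control libraries overlapped, so thinning had little difference to remove. The peak set was not made again from thinned libraries. With the offset per 10 Mb window 32387 regions were called, 89.4% of the number before and above the bound of 80% written for it. By that measure the offset argues against copy number over such windows as the whole cause. The number includes regions that were not called before the offset. Only 27946 regions, 77.1% of those called before, kept their call and direction. That share lies below the bound of 80% and above the 50% written for copy number as the cause, so by this measure the test does not decide. Changes narrower than the windows were not tested. Copy number could account for calls that the offset ended: Twist1 went from -0.72 ± 0.13 to -0.21 ± 0.13 (adjusted p = 0.242) and Spry4 from -0.80 ± 0.14 to -0.37 ± 0.14 (adjusted p = 0.0519), as the fold change shrank and the SE did not grow. Loss of KDM5B and differences between clones that arose in culture both stay open, since the KO group is not known to hold more than 1 clone.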

How the results depend on the processing

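The tests without mitochondrial regions, with thinned libraries, with at least 1 CPM, and of lists with the copy-number offset were chosen after seeing the data. Of 80 alternative counts of changed regions, 59 stayed within 1.5 times the reported count. An absolute log2 fold change of at least 1 gave 17592, 14803, 10108 and 18541 regions for the first 4 contrasts, because it only removes calls, and loess offsets gave 520 for the difference of responses, for which the cause was not tested. With 1 library left out, the counts ran from 21883 to 30925 and from 13775 to 24969 for KO against control without and with IFNG, from 9523 to 17722 and from 23152 to 30370 for IFNG in control and KO cells, and from 74 to 2049 for the difference. These fits have 1 library in a group and assume that it varies like the others.

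Of 80 shares of regions that were higher, 2 reversed: IFNG in control cells with library totals alone (36.7%), where the median of all regions was -0.19, and the difference of responses without control replicate 1 (41.6%, the lowest of a range to 85.5% with 1 library left out), for which the cause was not tested. A share counted as reversed when it crossed an even split and moved by over 10 points. Smaller crossings occurred for KO against control without IFNG with the DESeq2 Wald test (47.1%), DESeq2 size factors (49.5%), the replicate term (49.8%) and without control replicate 2 (45.9%), and with IFNG with the DESeq2 Wald test (48.8%). A term for the replicate number gave 36353, 31219, 20982, 38566 and 888 regions, although the numbers do not pair the samples.

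Of 20 alternative odds ratios, that of regions lower in untreated KO cells reversed to 1.00 with a 500 bp window (adjusted p = 0.969), and with IFNG it weakened to 0.965 (adjusted p = 0.257); the cause was not tested. Of 23 list calls, 19 were lost with an estimated correlation, 10 with all regions within 50 kb and 3 with library totals alone, and none reversed. List calls gained were 7 with all regions within 50 kb, 1 with library totals alone and 4 with the copy-number offset, and 0 with an estimated correlation or the replicate term. Of 2229 values of named genes none reversed, where a change of sign counted only if the gene passed in the main fit or under the other setting. Sign changes of genes that passed in neither were not counted. Of these 2229 values 35 lost the threshold, 13 of them with the copy-number offset, and 4 gained it, all for Kdm5b. Its fold change was -0.49 for untreated KO against control without KO replicate 2, 0.41 with IFNG with library totals alone, and -0.51 and -0.42 for IFNG in control cells with library totals alone and loess offsets, for which the cause was not tested. The removal of the filter moved nothing and decides nothing. Motif and repeat tests were not run, for want of a genome sequence.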

Other observations

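The tests of runs and of mitochondrial regions were chosen after the data had been seen, while the regions within 50 kb of list genes were planned. In KO cells there were 27 runs of at least 8 neighbouring regions, each at least 2-fold higher in KO cells both without and with IFNG, and 0 runs of lower regions by the same edgeR calls. At an unadjusted edgeR p under 0.05 there were 53 such runs of higher and 1 of lower regions, and with DESeq2 10 and 0. The number of runs that chance gives was not computed, and regions at least 2-fold higher outnumbered those lower (12085 and 5507 without IFNG). The longest run held 20 regions along Cdh12, a cadherin gene, with medians of 2.34 without and 2.53 with IFNG. A run of 19 regions covered Plxdc2 and Nebl (2.74 and 2.68), 18 regions lay along Bicc1 (2.41 and 2.08), 15 along Grm5 and Ctsc (3.09 and 3.24), 15 along Robo1, an axon guidance receptor gene (1.91 and 2.17), and 13 along Rarb (3.11 and 2.93). The run over Grm5 and Ctsc lies next to Rab38 on chromosome 7.

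With IFNG there were 3 such runs in control and KO cells alike, over Gbp4 (10 regions, medians of 2.87 and 3.50), over Gbp10 and Gbp6 (14 regions, 2.97 and 3.22) and over Gm12250, Igtp and Irgm2 (12 regions, 3.09 and 3.47). Of the 143 regions within 50 kb of the GTPase genes, 115 rose with IFNG in control and 119 in KO cells. The 12 mitochondrial regions were lower in KO than in control cells given IFNG, all past the threshold, with a median of -2.78. They follow the mitochondrial share of each library, so the 12 calls are not independent of each other. That share was 6.85% and 5.66% in control and 1.61% and 0.591% in KO libraries given IFNG. Without IFNG 0 of 12 passed with edgeR, 0 at an unadjusted p under 0.05 and 2 with DESeq2, at a median of -1.35.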
